A study of Mus musculus with 2 samples.

How the data were processed

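The series holds 2 droplet single-cell RNA libraries from mouse hippocampus, 1 from Mr1+/+ mice and 1 from Mr1-/- mice. The mice were 7 months old and untreated. Per the labels' protocols, hippocampi were dissociated with a primary neuron isolation kit, the cells were stained with DAPI (a dye that enters dead cells) and Draq5 (a DNA dye that marks nucleated cells), and DAPI-negative, Draq5-positive cells were sorted. Libraries were made with a 10x Genomics 5' gene expression kit, per the labels. This kit captures the 5' end of transcripts and tags each molecule with a unique molecular identifier (UMI). The series title calls the cells non-neuronal. How many mice were pooled in each library is not given in the sources used here.

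The values deposited by the authors are raw UMI counts per gene and cell barcode, with no normalization. The file headers name Cell Ranger 3.1.0, per the matrix header, while Cell Ranger 5.1.0 is named per the submitters' processing notes. These notes also name STAR and the mm10 build. The annotation release used for counting is not given in the sources used here. The smallest UMI count of a barcode was 501 in both libraries, and no rule for keeping barcodes is stated. CPM (UMI counts scaled to a common total), percent shares and ratios, on a linear or log2 scale, were computed here from the deposited counts. Gene positions come from the GENCODE M21 annotation of mm10, in which 30934 genes of the deposited tables were found by gene ID.

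Cells with at least 300 detected genes and at most 10% mitochondrially encoded UMIs were kept. Scrublet, run on each library with an expected rate of 0.05, called 335 of 6327 Mr1+/+ cells (5.29%) and 171 of 5278 Mr1-/- cells (3.24%) as doublets, and these were removed. The remaining 5992 and 5107 cells were normalised to a total of 10000 per cell, log transformed and scaled (maximum 10), using genes seen in at least 5 cells. The 2000 most variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 with a random seed of 7, without any integration of the libraries. The software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

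No cell annotation by the authors was used here. Each of the 23 clusters was named from marker genes, which were fixed before the data were examined, as were the gene lists, the rule for naming genes and the alternative settings. A marker counted as detected if at least 10% of a cluster's cells had a UMI of it. A cluster stayed unnamed if fewer than 3 markers were detected, if its 10 leading genes by fold went against its name, or if its median UMI count was under its library's median divided by 3 with no marker among those 10 genes. Such names mean only that a cluster carries a cell type's markers, and they can differ from the study's own names. By the naming rule no named cluster can have more markers of another class than of its own among its 10 leading genes. This gives the names no added support, and some endothelial-like and oligodendrocyte-like clusters had 0 markers of their own class there.

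UMIs were summed over the cells of each class and library and divided by the class total to give CPM. With 1 library per genotype there is no replicate, so no test, p-value or standard error was computed, and no result has a replicate check. Summed counts carry exact 95% Poisson intervals, shares carry exact (Clopper-Pearson) 95% binomial intervals, and ratios of CPM carry exact 95% intervals from the conditional binomial distribution. The difference of 2 shares carries a 95% Newcombe interval. These intervals and the limits given for counts of 0 (3 counts of the total) cover counting error only. They leave out differences between mice, dissections, sorts and library preparations, which cannot be separated from genotype here. Ratios are Mr1-/- over Mr1+/+.

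Classes with at least 50 cells in each library were compared (7 classes), and 5 of them had at least 200 cells in each. In each class, genes with a mean of at least 50 CPM, at least 50 UMIs over both libraries and at least 0.2 times the CPM of the class where the gene was highest were ranked by the ratio after adding 10 CPM. The last condition is meant to limit free RNA from other cells, and does not remove it. Mitochondrially encoded, ribosomal protein, haemoglobin and sex-linked genes were left out of the ranking. Up to 12 of the highest and 12 of the lowest genes were named in microglia-like cells, 5 and 5 in the other large classes, and 3 and 3 in the smaller classes. Within a list, up to 4 members with the most UMIs and those with the largest ratio each way could be named.

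31 gene lists were examined: homeostatic microglia, disease-associated microglia, interferon response, MHC class I and class II presentation, inflammatory cytokine and NF-kB, complement and phagocytic receptor, lysosome, immediate early, heat shock, antioxidant, NADPH oxidase, nuclear and mitochondrially encoded oxidative phosphorylation, cytosolic ribosomal protein, glycolysis, cell cycle, TGF-beta signalling, pan-reactive, A1-type and A2-type astrocyte, astrocyte homeostasis, cholesterol synthesis, myelin, endothelial barrier and transport, endothelial activation, MAIT-associated, sex-linked, haemoglobin, neuronal and choroid plexus transcripts. A list was read in a class where at least 3 members reached 20 CPM as the mean of both libraries. Its median log2 ratio, with 1 CPM added, was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The range that holds the central 95% of the random medians is called the random range below. It describes these libraries and treats genes as independent, so it is no test of genotype. Of 142 list and class pairs, 37 lay outside this range, where 7.1 would by chance. The share of a list among a cell's UMIs was also computed after thinning every cell to 1500 UMIs and leaving out shallower cells.

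The computation was tested on simulated data drawn from the real class sums. In microglia-like cells (6043 genes, 200 changed), genes simulated at 1.5-fold gave a median of 1.51 and their intervals excluded 1 in 96.0%, while genes at 2.0-fold gave 1.98 and 100% did. The intervals held the true ratio in 95.2%. In astrocyte-like cells (6562 genes, 200 changed) the medians were 1.45 and 2.02, and 68.0% and 98.0% of the intervals excluded 1. There 95.8% of the intervals held the true ratio. The simulated sums were independent Poisson counts, so coverage near 95% was built in and only the computation was checked. UMIs that gather in few cells and differences between libraries were left out. The shares above are therefore not those to be had in the real comparison.

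The alternative settings were at least 500 genes per cell, at most 5% or 20% mitochondrial UMIs, called doublets kept, Leiden resolution 0.5 or 2.0, clustering without stress, ribosomal, mitochondrial, haemoglobin and sex-linked genes, median-of-ratios scaling, a total without these gene groups, each cell weighing the same, cells thinned to 1500 UMIs, a prior of 1 CPM for ranking, list members at 5 or 100 CPM or more, all barcodes for single genes, and thinning to 1000 UMIs or none for shares per cell. Settings that use parts of the microglia-like class were added after the data had been seen. An alternative counted as having moved a list median if the change exceeded 0.5 times the width of its random range, a share of cells or the log2 ratio of a gene if it left its 95% interval, and a share per cell if it changed by more than 0.1 of its level.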

Results

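Gene expression was measured in single hippocampal cells of 7-month-old Mr1+/+ and Mr1-/- mice to describe, for each cell type, which transcripts differ between the genotypes. Mr1 encodes a molecule related to MHC class I that presents vitamin B metabolites to mucosal-associated invariant T (MAIT) cells. Each genotype was represented by 1 library. The Mr1+/+ library held 6410 barcodes with 23244575 UMIs, and the Mr1-/- library held 5347 barcodes with 18349132 UMIs. The median barcode had 3160 UMIs and 1618 genes in the Mr1+/+ library and 2935 UMIs and 1521 genes in the Mr1-/- library. Median mitochondrial shares were 2.81% and 2.87%. After filtering, 5992 Mr1+/+ cells and 5107 Mr1-/- cells were clustered. None of the differences below has a replicate check, and each is a difference between these 2 libraries.

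Mr1 transcripts were nearly missing from the Mr1-/- library. Over the kept cells, 130 Mr1 UMIs (95% Poisson interval 109 to 154) were counted in the Mr1+/+ library and 2 (0.242 to 7.22) in the Mr1-/- library. These correspond to 6.06 and 0.115 CPM and a ratio of 0.019 (0.0023 to 0.0702). With all barcodes the counts were 139 and 2. In the Mr1+/+ library the UMIs were spread over astrocyte-like cells (53 UMIs, 17.4 CPM), microglia-like cells (30, 7.74 CPM), endothelial-like cells (18, 5.19 CPM), mural-like cells (16, 5.91 CPM), oligodendrocyte-like cells (10, 1.58 CPM) and ependymal-like cells (3 UMIs). The 2 UMIs of the Mr1-/- library came from 1 endothelial-like and 1 neuroblast-like cell. Mr1 (ENSMUSG00000026471) lies on the minus strand of chromosome 1 from 155127277 to 155146814 in mm10. Which part of the gene was deleted is not given in the sources used here, and reads from the 5' end outside that part would still be counted.

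The sex-linked genes pointed to female mice in both libraries. Xist, the RNA of the inactive X chromosome, gave 9366 UMIs in the Mr1+/+ library and 6768 in the Mr1-/- library (ratio 0.895, 0.867 to 0.923). Its antisense partner Tsix, whose reads overlap those of Xist, gave 61 and 28 UMIs (ratio 0.568, 0.350 to 0.903). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d had 0 UMIs in both libraries, where a count of 0 allows up to 3.

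T cells, which include the MAIT cells that recognise Mr1, were not detectable at this depth in either library. No cell carried 3 or more T or NK cell markers, which allows a share of such cells of up to 0.0501% of 5992 Mr1+/+ cells and 0.0587% of 5107 Mr1-/- cells. A T cell with fewer detected markers would not be counted, so this does not limit the share of all T cells. B cells and monocytes or dendritic cells were likewise at 0 in both libraries, with the same limits. Of the MAIT-associated list, Trav1 (the invariant receptor segment), Cd3e, Tbx21, Il23r, Il17a, Blk and Klrb1 had 0 UMIs in both libraries, and so did the T cell genes Cd3g and Trbc2. Cd3d gave 1 and 1 UMI, Icos 7 and 0, Ccr6 2 and 6, Il18r1 1 and 0, Il18rap 0 and 2, and Cxcr6 1 and 0. Of the list's more abundant members, Zbtb16 gave 395 and 241 UMIs (ratio 0.755, 0.641 to 0.889), Maf 1646 and 1718 (1.29, 1.21 to 1.38), Il7r 195 and 203 (1.29, 1.05 to 1.58) and Trac 56 and 49 (1.08, 0.723 to 1.62), the last in 51 and 44 cells. Cells with 3 or more markers of other rare types were 11 and 14 for border macrophages, 1 and 1 for neutrophils, 19 and 9 for choroid plexus epithelium and 1 and 1 for erythroid cells.

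The 23 clusters were named as 10 cell classes by their markers, and the endothelial-like, mural-like and microglia-like classes took a larger share of the Mr1-/- library. Endothelial-like cells made up 22.4% of the Mr1+/+ cells (95% interval 21.3 to 23.5) and 29.5% of the Mr1-/- cells (28.2 to 30.7), a difference of 7.05 percentage points (5.41 to 8.70). Mural-like cells, the pericytes and smooth muscle cells of vessels, made up 16.1% and 19.0% (difference 2.91 points, 1.48 to 4.35), and microglia-like cells 12.2% and 15.4% (3.21 points, 1.91 to 4.52). Astrocyte-like cells were fewer in the Mr1-/- library, at 9.34% (8.56 to 10.2) against 16% (15% to 16.9%), a difference of -6.61 points (-7.85 to -5.38). Oligodendrocyte-like cells made up 24.2% and 19.0% (-5.19 points, -6.72 to -3.64). Neuron-like cells made up 4.59% and 3.25% (-1.34 points, -2.07 to -0.604). Neuroblast-like cells (1.10% and 1.06%), oligodendrocyte precursor-like cells (0.701% and 0.646%) and fibroblast-like cells (0.484% and 0.627%) had differences whose intervals held 0. Ependymal-like cells made up 0.751% and 1.16% (0.404 points, 0.031 to 0.794).

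Shares sum to 100%, so a class can be lower because others are higher. Without the endothelial-like class, the shares were 31.2% and 27.0% for oligodendrocyte-like cells, 20.8% and 27.0% for mural-like cells, 15.7% and 21.8% for microglia-like cells and 20.6% and 13.2% for astrocyte-like cells. Dissociation and the sort for live nucleated cells set which cells entered the libraries, so the shares are not those of the tissue. Clusters with fewer UMIs than the rest of their class held 121 and 56 of the microglia-like cells, 213 and 69 of the oligodendrocyte-like cells and 89 and 17 of the astrocyte-like cells, with median UMI counts of 1121 and 1204, 1157 and 2222, and 890 and 947. Among cells with at least 1500 UMIs (5148 and 4582), the shares were 22.5% and 29.1% for endothelial-like, 25.3% and 20.7% for oligodendrocyte-like, 15.6% and 16.9% for mural-like, 12.2% and 16.1% for microglia-like and 16.5% and 9.89% for astrocyte-like cells. With at most 5% mitochondrial UMIs the mural-like difference was 1.31 points. An unnamed cluster of shallow cells, led by genes that include the vascular receptors Adgrl4 and Calcrl, held 1.54% and 1.06% of the cells.

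**Figure D1:**
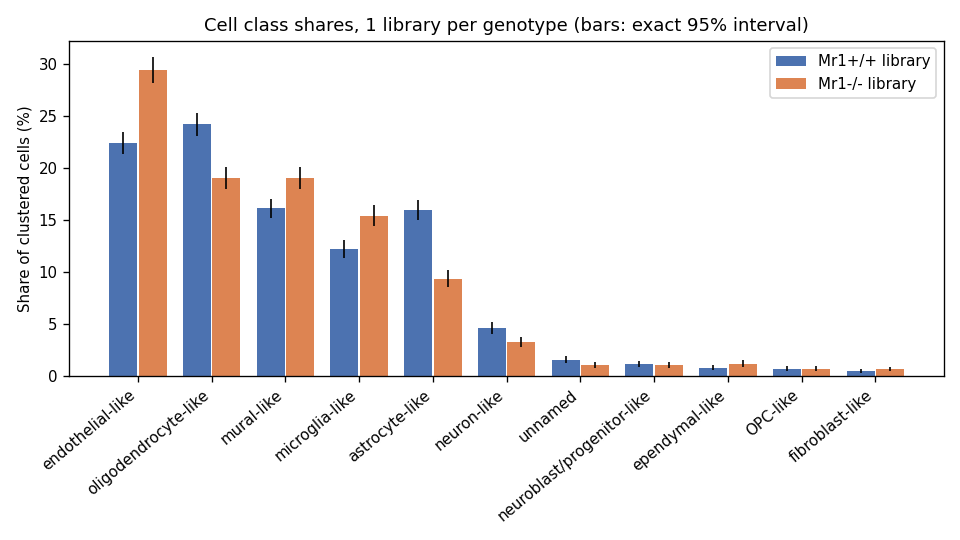
Share of clustered cells (%, y axis) in each marker-named class (x axis) of the Mr1+/+ library (5992 cells) and the Mr1-/- library (5107 cells), with exact 95% binomial intervals as error bars. Endothelial-like cells took 22.4% and 29.5% of the cells and astrocyte-like cells 16% and 9.34%.

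Microglia-like cells, the brain's resident macrophages, were compared first (730 Mr1+/+ and 786 Mr1-/- cells). Among the genes ranked highest in the Mr1-/- library were the chemokine genes Ccl4 and Ccl12 and the immediate early gene Fos. Ccl4, a chemokine that attracts immune cells, was at 365 CPM in the Mr1-/- library and 196 CPM in the Mr1+/+ library (ratio 1.86, 95% counting interval 1.70 to 2.03), and the chemokine Ccl12 was at 124 and 84.4 CPM (1.47, 1.28 to 1.70). Cd74, the invariant chain of MHC class II, was at 122 and 71.8 CPM (1.70, 1.47 to 1.98), a difference carried by border macrophages as described next. The immediate early transcription factor Fos was at 261 and 159 CPM (1.64, 1.48 to 1.81), and Hk2, a hexokinase of glycolysis, was at 338 and 236 CPM (1.43, 1.31 to 1.56).

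Lower in Mr1-/- microglia-like cells were Ddit4, a stress-induced inhibitor of mTORC1 signalling, at 62.7 against 169 CPM (ratio 0.372, 0.320 to 0.431), and Fkbp5, a co-chaperone of steroid receptors, at 65.7 against 123 CPM (0.535, 0.458 to 0.623). The heat shock co-chaperone Dnaja1 was at 203 against 317 CPM (0.640, 0.585 to 0.70). A UMI of Ddit4 was found in 337 of 730 Mr1+/+ and 184 of 786 Mr1-/- microglia-like cells. Free RNA can enter such counts, and its share was not measured. Ddit4 was more abundant in endothelial-like cells (678 and 334 CPM) and lower there too, as was Cd2ap (228 and 165 CPM). Further genes on the higher side were Rnaset2a, Gm38843, Gm10138, Sppl3, Ube2v1 and Ier2, with ratios from 1.39 (Ier2) to 1.85 (Rnaset2a). Those on the lower side were Cd2ap, Rbbp9, Evi2a, Abhd17c, Traf5, Timm10b, Mat2b, Cysltr1 and Usp8, with ratios from 0.545 (Cd2ap) to 0.738 (Usp8). Sppl3 was also higher in mural-like (log2 ratio 0.77), oligodendrocyte-like (0.68), endothelial-like (0.34) and neuron-like cells (0.24). It was lower in astrocyte-like (-0.03) and neuroblast-like cells (-0.45). Rnaset2a was also higher in endothelial-like (1.13) and astrocyte-like cells (0.98), at fewer CPM. Timm10b was lower in all other classes compared, from -0.09 (endothelial-like) to -0.81 (neuron-like). So was Mat2b, from -0.03 (mural-like) to -0.4 (neuroblast-like). Rnaset2a has a near-identical copy, Ube2v1 shares exons with a read-through gene, and Gm10138 is antisense to another gene, so their counts are uncertain. Gm10138 also lies on chromosome 1 within 20 Mb of Mr1.

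A few cells carried much of the Cd74 and Ccl12 differences. The 5 Mr1-/- cells with the most Cd74 held 381 of its 489 UMIs, against 135 of 278 in the Mr1+/+ library, and Cd74 was found in 81 of 786 and 90 of 730 cells. For Ccl12 the 5 highest cells held 208 of 497 and 85 of 327 UMIs. With up to 20% mitochondrial UMIs, 8 Mr1+/+ and 12 Mr1-/- cells of this class formed a border macrophage cluster led by Cd74 and Pf4. These cells held 56 of the 278 and 287 of the 489 Cd74 UMIs. Without them the log2 ratio of Cd74 was -0.17, and in the cluster led by the homeostatic gene P2ry12 alone it was -0.41, so Cd74 was not higher in the remaining microglia-like cells. Ccl4, Ccl3 and Ccl12 were among the 10 leading genes of the other large microglia-like cluster, which held 36.9% of the Mr1+/+ and 44.7% of the Mr1-/- microglia-like cells. Cell mix therefore enters the ratios of these genes and of the NF-kB list, and the size of a cluster that Ccl4 helps define is not read as a result. Ccl4 was found in 159 of 730 and 220 of 786 cells. The log2 ratio of Ccl4 (0.90) was 0.33 with each cell weighing the same, that of Ier2 (0.47) was 0.09 after thinning, and that of Fos (0.71) was 0.04 in the P2ry12-led cluster alone. Border macrophage or neutrophil markers were carried by 11 and 14 microglia-like cells.

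**Figure D2:**
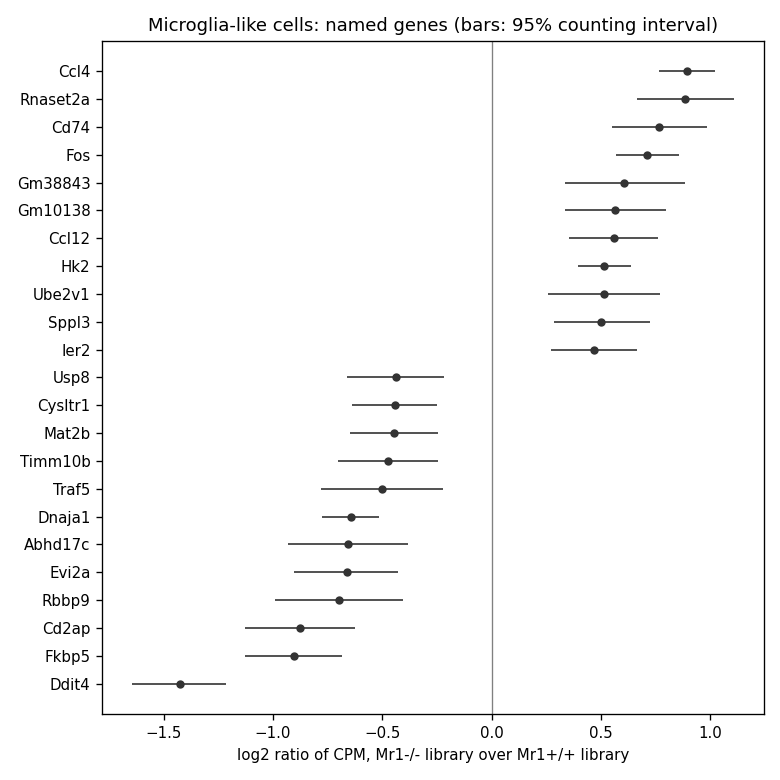
log2 ratio of CPM (x axis, Mr1-/- over Mr1+/+) of genes ranked highest and lowest (y axis) in microglia-like cells, with 95% counting intervals as bars. Each point is 1 gene from the summed UMIs of 1 library per genotype, and ratios ran from 0.372 for Ddit4 to 1.86 for Ccl4.

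Of the gene lists in microglia-like cells, immediate early genes lay above the random range. Of 19 measured members 14 were higher and 5 lower in the Mr1-/- library (median log2 ratio 0.24), among them Jun (992 against 801 CPM, ratio 1.24), Junb (1.17), Jund (1.19) and Egr1 (1.96), while Rhob (0.909) and Cebpb (0.849) were lower. The inflammatory cytokine and NF-kB list was also above its range (median 0.11, 10 higher and 8 lower of 18). In it Ccl4, Bcl2a1b (1.19) and Cd83 (1.11) were higher, and Nfkbia, an inhibitor of NF-kB (0.855), and Il18 (0.835) were lower. In the P2ry12-led cluster alone this median was -0.03. The MHC class II list was above its range (median 0.23, 4 of 5 members higher) through Cd74 and H2-Ab1 (132 against 69 UMIs, ratio 1.85, 1.37 to 2.52). H2-Oa had a ratio of 1.17, while H2-DMa (1.01) and H2-DMb1 (0.981), which load peptides, differed by less than counting error. Without the border macrophage cells the MHC class II median was -0.02, so this list was not higher in the remaining microglia-like cells.

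Heat shock genes lay below the random range in microglia-like cells, with 9 of 12 members lower (median -0.19). The chaperones Hspa8 (ratio 0.871), Hsp90ab1 (0.847) and Hspa5 (0.797) were lower, and the stress-inducible Hspa1a (1.15) and Hspa1b (1.23) were higher. Cytosolic ribosomal protein genes were above the range, with 72 of 77 members higher (median 0.10), such as Rps29 (1.21) and Rpl13a (1.47). The ribosomal share of a cell's UMIs had a median of 6.80% in the Mr1-/- library and 6.40% in the Mr1+/+ library after thinning. Nuclear oxidative phosphorylation genes were slightly higher, with 59 of 81 above 1 (median 0.06), such as Cox8a (1.11) and Ndufa1 (1.26). Of the mitochondrially encoded genes 10 of 12 were higher (median 0.10), such as mt-Co1 (1.05), and with each cell weighing the same this median was -0.01. The overlapping genes mt-Atp8 (1.64) and mt-Atp6 (0.501) share sequence, between which counting can split reads.

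The signature genes of microglial state stayed inside the random range. The homeostatic list had a median of -0.01 (7 higher and 13 lower of 20), with Cst3 (1.01) and P2ry12 (0.969) near 1, Mef2c at 1.09 and Entpd1 at 0.895. The disease-associated list had a median of 0.02 (10 of 16 higher), with Tyrobp at 1.04, Ctsd at 0.922 and Ccl6 at 1.18. Medians were 0.01 for the interferon response (6 of 12 higher, Bst2 1.14), 0.07 for MHC class I (10 of 10 higher, B2m 1.04 and H2-K1 1.09), 0.06 for TGF-beta signalling (8 of 10 higher), -0.02 for complement and phagocytic receptors (8 of 17 higher) and -0.01 for the lysosome (9 of 25 higher). They were -0.01 for antioxidant genes (11 of 24 higher), -0.02 for glycolysis (4 of 13 higher), -0.02 for the cell cycle (2 of 5 higher) and 0.02 for endothelial barrier genes (4 of 7 higher, mean -0.01). The NADPH oxidase list (3 of 6 higher) and the A1-type list (3 of 6 higher, with Fkbp5 among its members) were near 0. The homeostatic, complement, lysosome, antioxidant, NADPH oxidase, glycolysis, cell cycle and A1-type medians, all below 0, lay above 0 with median-of-ratios scaling. With each cell weighing the same the interferon median was 0.33. After thinning to 1500 UMIs the medians were 0.24 for interferon, 0.13 for the A1-type list and -0.12 for glycolysis, so these 3 lists depended on this setting. Thinning also left out 101 Mr1+/+ and 47 Mr1-/- shallower cells, so an effect of depth was not told apart from their loss. Myelin transcripts in microglia-like cells had a median of 0.02 and a mean of -0.52, with Mbp, a protein of oligodendrocytes, at a ratio of 0.628.

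Endothelial-like cells (1342 and 1504) had higher MHC class I transcripts and lower heat shock, immediate early and activation transcripts in the Mr1-/- library. Of the 13 measured members of the MHC class I list, 12 were higher (median log2 ratio 0.35, above the random range). The list holds class I molecules, which present peptides to CD8 T cells, and genes that act before presentation, such as Tap1 and Psmb9. H2-K1 was at 942 against 722 CPM (ratio 1.31, 1.24 to 1.37), H2-D1 at 979 against 826 CPM (1.19, 1.13 to 1.25), B2m at 768 against 576 CPM (1.33, 1.26 to 1.41) and the immunoproteasome subunit Psmb9 at 174 against 115 CPM (1.51, 1.33 to 1.72). H2-Q6 had a ratio of 1.72 and H2-T23 of 0.934. The list's share of a cell's UMIs had a median of 0.358% against 0.284% before thinning. The quartiles before thinning were 0.235% against 0.185% and 0.516% against 0.428%. After thinning the median was 0.333% against 0.267%, a step of 1 UMI, so no order is read from that median. The mean after thinning was 0.408% against 0.326%. Class I genes are close copies of each other, which counting could split. Interferon response genes were inside the range (median 0.06, 14 of 20 higher), with Ifitm3 at 1.05 and Isg15 at 1.25. At Leiden resolution 2.0 an endothelial-like cluster led by Ifit3 and Isg15 held 171 Mr1+/+ and 259 Mr1-/- cells. The MHC class I ratios were not computed without this cluster, so whether cell mix enters them was not tested.

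Ctla2a, a cathepsin inhibitor-like gene, was at 426 CPM in Mr1-/- endothelial-like cells and 883 CPM in Mr1+/+ cells (ratio 0.483, 0.454 to 0.513), and Ddit4 at 334 and 678 CPM (0.492, 0.459 to 0.528). Dusp1, a MAP kinase phosphatase, was at 244 and 448 CPM (0.545, 0.501 to 0.593). Tmem252 (0.498) and the transcription factor Cebpd (0.548) completed the lower side. Besides Psmb9, the higher side held Fam177a (1.66), 1810009A15Rik (1.58), Ube2v1 (1.56) and Rtl8b (1.56), a gene with close copies. In the other classes compared, 1810009A15Rik was higher too, with log2 ratios from 0.36 (oligodendrocyte-like) to 1.2 (neuroblast-like). So was Ube2v1, from 0.23 (neuron-like) to 0.67 (astrocyte-like). Ctla2a and Tmem252 were also leading genes of endothelial-like clusters. Heat shock genes were lower in 11 of 12 cases (median -0.32, below the range), with Hspa8 at 0.710 and Dnaja1 at 0.631. Immediate early genes were lower in 13 of 19 (median -0.19, below the range), with the flow-responsive factor Klf2 at 1932 against 2772 CPM (0.697), Rhob at 0.748 and, on the other side, Fos at 1.67. Dusp1 and Cebpd belong to this list. A cell's share of immediate early UMIs was 0.600% against 0.80% after thinning, and of heat shock UMIs 0.600% against 0.733%, with 170 Mr1-/- and 182 Mr1+/+ cells left out.

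Endothelial activation genes were lower in 6 of 8 (median -0.28, below the range), with Ctla2a, Vwf (0.779) and Edn1 (0.823) lower and Plvap (1.16) and Cxcl12 (1.06) higher. The cluster whose leading genes include Vwf held 7.0% of the Mr1+/+ and 4.32% of the Mr1-/- endothelial-like cells, and the cluster with Plvap 2.24% and 3.39%, so cell mix enters these ratios. The barrier and transport list stayed inside the range (median -0.04, 5 of 18 higher). Within it the tight junction gene Cldn5 had a ratio of 1.19 (1.17 to 1.22), and the glucose transporter Slc2a1 was at 1356 against 2068 CPM (0.656, 0.632 to 0.680). Nuclear oxidative phosphorylation genes were higher in 66 of 80 (median 0.08) and mitochondrially encoded genes in 11 of 13 (median 0.08), both above the range. Of the 5 pan-reactive genes seen here 4 were lower (median -0.18). All 6 measured myelin transcripts were lower (median -0.48), with Mbp at 0.633 and Mal at 0.701. Oligodendrocyte-like cells, which make these transcripts, were also fewer in the Mr1-/- library (19.0% against 24.2%). With myelin members at 100 CPM or more the median was -0.16. Of the 191 Mr1+/+ haemoglobin Hbb-bs UMIs in this class 189 lay in 1 cell, and the Mr1-/- library had 14.

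Oligodendrocyte-like cells, which make myelin, showed lower Sgk1 and similar myelin gene expression (1450 and 971 cells). Sgk1, the serum and glucocorticoid regulated kinase, was at 894 CPM in the Mr1-/- library and 2147 CPM in the Mr1+/+ library (ratio 0.416, 0.401 to 0.432). The transcription factor Klf9 was at 133 and 232 CPM (0.570, 0.517 to 0.629), Polr3e, a subunit of RNA polymerase III, at 228 and 491 CPM (0.463, 0.431 to 0.498) and Sys1, a Golgi protein, at 43.2 and 128 CPM (0.337, 0.286 to 0.396). Sys1 was also lower in mural-like (log2 ratio -1.27), astrocyte-like (-0.79), neuron-like (-0.55) and neuroblast-like cells (-2.03), so its difference was not particular to this class. Mrps6 (0.511) shares exons with Slc5a3, so its count is uncertain. Among the higher genes were Dcaf17 (1.59), Rtl8b (1.55), Dynlt1b (1.42) and Fam177a (1.37). Dynlt1b has close copies.

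The myelin list was inside the random range in oligodendrocyte-like cells (median 0.03, 12 of 20 higher), with Mal at 0.999, Mbp at 0.939, Trf at 0.819 and Klk6 at 1.27. So was the cholesterol synthesis list, which feeds myelin (6 of 13 higher), whose median near 0 turned sign with other scalings. All 10 heat shock genes were lower (median -0.27), with Hspa8 at 0.849 and Dnajb1 at 0.603. Immediate early genes lay just above the range (median 0.09, 5 of 8 higher), with Jund at 1.29, Rhob at 1.18 and Nr4a1 at 0.690. With members at 100 CPM or more this median was 0.24. Mitochondrially encoded genes were higher in 12 of 13 (median 0.08) and disease-associated genes in 10 of 11 (median 0.07, Apoe 1.05), while astrocyte homeostasis genes were lower (median -0.14, 6 of 9 lower, Clu 0.585). The astrocyte-like share was also lower in the Mr1-/- library (9.34% against 16%), and with members at 100 CPM or more this median was -0.03. Nuclear oxidative phosphorylation genes were inside the range (median 0.02). Of the choroid plexus list only Enpp2 (0.913) and Ttr (124 against 201 UMIs, ratio 0.923) were measured.

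Astrocyte-like cells (956 and 477) had fewer Dio2, Kcnn2 and Gfap transcripts in the Mr1-/- library. Dio2, the enzyme that turns thyroxine into its active form, was at 56.0 against 109 CPM (ratio 0.514, 0.399 to 0.657), and the potassium channel gene Kcnn2 at 91.5 against 164 CPM (0.559, 0.458 to 0.677). Cebpd was at 71.0 against 126 CPM (0.565, 0.451 to 0.704). The lower side also held Mpv17 (0.455) and Mrps6 (0.543), and the higher side Hist2h2aa1 (2.0), Pola2 (1.96), Rab11fip4 (1.89), Ube2v1 (1.60) and Gm15417 (1.55). Hist2h2aa1 has a near-identical copy and Gm15417 is antisense to another gene, so both are uncertain. So is Mpv17, whose exons overlap another gene. Mpv17 was lower in all other classes compared, with log2 ratios from -0.52 (mural-like) to -1.92 (neuroblast-like). Mrps6 was lower in all of them too, from -0.6 (neuroblast-like) to -1.06 (mural-like).

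The 3 measured pan-reactive genes were lower in astrocyte-like cells (median -0.39, below the random range): Gfap, the filament of reactive astrocytes, at 143 against 200 CPM (ratio 0.716, 0.609 to 0.839), Vim (0.762) and S100a6 (0.936). With called doublets kept this median was -0.05, and after thinning the list's median share per cell was 0% in both libraries. Astrocyte homeostasis genes were inside the range (median -0.06, 6 of 17 higher), with Clu at 0.941, Slc1a2 at 1.01 and S100b at 1.20. Of the A1-type list 2 genes and of the A2-type list 1 gene (S100a10, 0.825) were measured, too few for a median. Nuclear oxidative phosphorylation genes were above the range (median 0.07, 64 of 85 higher), and the mitochondrially encoded list was inside it (median 0.01, mean -0.08). Immediate early (0.03), heat shock (-0.08) and cholesterol synthesis genes (-0.01, 8 of 18 higher) were also inside. The 4 measured myelin transcripts were lower (median -0.45), with Mbp at 0.613, beside the lower oligodendrocyte-like share.

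Mural-like cells (965 and 971) had lower heat shock transcripts in the Mr1-/- library, with 11 of 12 lower (median -0.31, below the random range), among them Hspb1 (0.820), Hspa8 (0.841) and Hsph1 (0.518), while Hspa1a was at 1.41. Klf15, a transcription factor of smooth muscle, was at 38.1 against 65.0 CPM (0.586, 0.451 to 0.758), and Ptgis, the prostacyclin synthase, which also led a mural-like cluster, at 149 against 237 CPM (0.628, 0.551 to 0.716). That cluster held 18.4% of the Mr1-/- and 23.6% of the Mr1+/+ mural-like cells, so cell mix enters this ratio. Mrps6 (0.480), Sumo3 (0.608) and Ccl19 (0.615), a chemokine with several gene copies, were also lower. Sumo3 was lower in endothelial-like (log2 ratio -0.89), neuron-like (-0.86), microglia-like (-0.65), oligodendrocyte-like (-0.6) and neuroblast-like cells (-0.26) too. The laminin chain Lamb1 (1.65), Tspan15 (1.71), the GTPase Rhod (1.55), Dynlt1b (1.5) and Ddx1 (1.49) were higher. Immediate early genes were lower in 10 of 17 (median -0.10, below the range), with Rhob at 0.930, Egr1 at 0.580 and Ier2 at 1.28. Mitochondrially encoded genes were higher in 11 of 13 (median 0.12), but with at most 5% mitochondrial UMIs this median was -0.04.

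**Figure D3:**
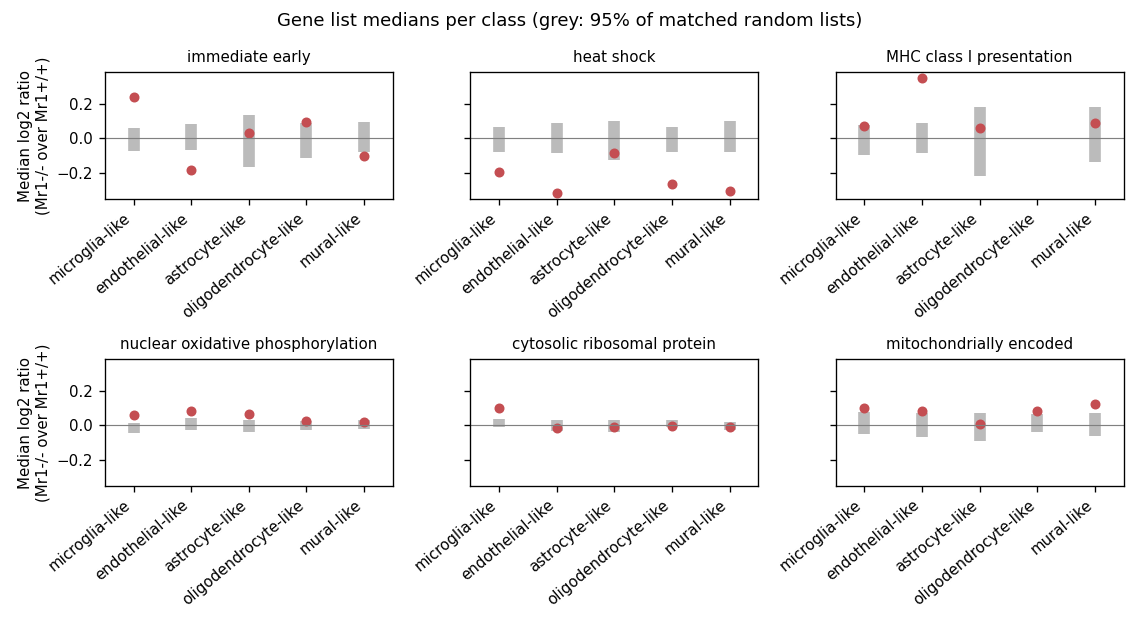
Median log2 ratio (y axis, Mr1-/- over Mr1+/+) of 6 gene lists in the 5 large classes (x axis), with grey bars for the range of 95% of 10000 matched random lists and no point where fewer than 3 members were measured. Heat shock medians ran from -0.32 in endothelial-like to -0.08 in astrocyte-like cells, and the immediate early median was 0.24 in microglia-like and -0.19 in endothelial-like cells.

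Neuron-like cells were few (275 and 166), as the series title describes non-neuronal cells, and single cells weighed on the sums. Their larger cluster was led by genes that include Reln, Ndnf and Nhlh2, which mark Cajal-Retzius cells. Photoreceptor and pineal genes ranked highest: Sag gave 211 against 4 UMIs (ratio 87.6, 33.7 to 324), Gnb3 213 against 0 and Pde6g 146 against 0, where a count of 0 allows up to 3. Within the class, all of these Mr1-/- UMIs lay in 5 cells, and the other Mr1-/- neuron-like cells had 0 UMIs of the 3 genes. Sag was also counted outside these 5 cells, with 82 UMIs in the Mr1-/- and 44 in the Mr1+/+ library. The neuropeptide gene Cck (0.367), the cannabinoid receptor gene Cnr1 (0.391) and Nap1l5 (0.398) ranked lowest. Of the Mr1+/+ UMIs 273 of 394 for Cck and 140 of 174 for Cnr1 lay in 1 cell. With each cell weighing the same the log2 ratio was near 0 for Cck and 0.61 for Cnr1.

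Neuronal transcripts were lower in 13 of 14 members in neuron-like cells (median -0.25, below the random range), with Gad1 at 0.154 and Snap25 at 1.03, and after thinning this median was -0.08. Heat shock genes were lower in 9 of 10 (median -0.24). Ribosomal protein genes were higher in 70 of 77 (median 0.13) and nuclear oxidative phosphorylation genes in 60 of 84 (median 0.09), the latter at -0.01 with up to 20% mitochondrial UMIs. Lysosome genes had a median of 0.16 and a mean of -0.14 (12 of 19 higher), and a median of -0.20 with each cell weighing the same. Microglial transcripts were lower, with medians of -0.87 over 4 homeostatic genes and -3.16 over 4 complement and phagocytic genes, C1qb at 4 against 83 UMIs among them. With at least 500 genes per cell these medians were -0.12 and -0.57, and with each cell weighing the same -1.70 and -5.46. Of the Mr1+/+ neuron-like cells 10 of 275 carried 3 or more microglia markers, against 0 of 166 Mr1-/- cells, and held 178 of the 463 UMIs of the complement list.

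Neuroblast-like cells (66 and 54) had more cell division transcripts in the Mr1-/- library. Cdk1, the mitotic kinase, gave 53 against 3 UMIs (ratio 18.7, 6.06 to 93.5), the replication factor Pclaf 125 against 11 (12, 6.49 to 24.7) and the histone gene Hist1h2ap 941 against 104 (9.57, 7.81 to 11.8). Hist1h2ap was also a leading gene of this cluster and has near-identical copies. All 15 cell cycle genes were higher (median 1.88, above the random range), with a median of 1.26 when each cell weighed the same. Cells with 3 or more genes of this list numbered 30 of 54 in the Mr1-/- library (55.6%, 41.4 to 69.1) and 29 of 66 in the Mr1+/+ library (43.9%, 31.7 to 56.7), at median UMI counts of 3213 and 3945. These cells held 2444 of 2994 and 1504 of 2351 UMIs of the list. The guidance gene Sema3c (0.324), the neuropeptide gene Tac2 (0.315) and the nucleoside transporter gene Slc29a1 (0.310) ranked lowest. At Leiden resolution 2.0 the class split into a cluster led by genes that include Neurod1 and Tac2 (42 and 29 cells) and a cluster led by Dlx1 (25 and 30 cells), so cell mix enters these ratios. Lysosome genes were lower (median -0.42, 13 of 17 lower), at -0.03 with Leiden resolution 2.0. Nuclear oxidative phosphorylation genes were just above the range (median 0.09, 53 of 85 higher) beside a median of -0.10 over all genes of this class. All 10 myelin transcripts were lower (median -5.65), and 2 of 66 Mr1+/+ cells with oligodendrocyte markers held 596 of their 633 UMIs.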

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

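The immediate early list, genes switched on within minutes of a stimulus, lay outside the random range in opposite directions in different classes. Its median log2 ratio (Mr1-/- over Mr1+/+) was 0.24 in microglia-like and 0.094 in oligodendrocyte-like cells and -0.19 in endothelial-like and -0.10 in mural-like cells. The lysosome list parted too, with 0.16 in neuron-like and -0.42 in neuroblast-like cells. This parting depended on the processing. The 2 medians were -0.006 and -0.027 with Leiden resolution 2.0, and 0.004 and -0.038 with at most 20% mitochondrial UMIs. The difference between the classes was not tested for either list.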

How the results depend on the processing

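No paired analysis was possible because each genotype had 1 library, and the replicate number 1 only follows the order of deposit. Values are median log2 ratios unless stated, and the cause was not tested for any of them.

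With Leiden resolution 2.0, neuron-like medians were -0.65 (complement), -0.20 (homeostatic microglia), -0.006 (lysosome, turned) and -0.005 (nuclear oxidative phosphorylation, turned). Neuroblast-like medians were -0.027 (lysosome), -4.63 (myelin) and 0.33 (nuclear oxidative phosphorylation). With at least 500 genes per cell, the neuron-like complement and homeostatic medians were -0.57 and -0.12.

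With at most 20% mitochondrial UMIs, Cd74 (-0.06) and MHC class II (-0.024) turned in microglia-like cells. In neuron-like cells nuclear oxidative phosphorylation turned (-0.006), and the lysosome (0.004), complement (-0.64) and homeostatic (-0.14) medians moved. Neuroblast-like medians were -0.038 (lysosome), -4.64 (myelin) and 0.33 (nuclear oxidative phosphorylation). With at most 5%, the mural-like mitochondrially encoded median turned (-0.044), the mural-like share differed by 1.31 points, and the neuron-like complement and homeostatic medians were -0.47 and -0.21.

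With called doublets kept, medians were -2.71 (neuron-like complement), 0.001 (neuron-like lysosome), -0.13 (microglia-like endothelial barrier), -0.34 (microglia-like myelin), -1.69 (neuroblast-like myelin) and -0.049 (astrocyte-like pan-reactive).

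With cells thinned to 1500 UMIs, Cck (0.015) and Cnr1 (0.83) turned in neuron-like cells, where the complement (-0.54), homeostatic (-0.32) and neuronal (-0.08) medians moved. Microglia-like medians were 0.13 (A1-type), 0.44 (MHC class II), -0.12 (glycolysis) and 0.24 (interferon), and 11 named microglia genes were shared with the ranking used above. Neuroblast-like myelin was -4.26.

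With each cell weighing the same, Cck (0.005) and Cnr1 (0.61), the neuron-like lysosome (-0.20) and the microglia-like mitochondrially encoded median (-0.013) turned. Other values were 1.26 (neuroblast-like cell cycle), -4.67 (neuroblast-like myelin), -5.46 (neuron-like complement), -1.70 (neuron-like homeostatic), 0.20 (neuron-like ribosomal), 0.33 (microglia-like interferon) and 14 shared named microglia genes.

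Median-of-ratios scaling gave 0.13 (microglia-like ribosomal) and 0.19 (neuroblast-like nuclear oxidative phosphorylation). Members at 100 CPM or more gave -0.025 (oligodendrocyte-like astrocyte homeostasis), 0.24 (oligodendrocyte-like immediate early), 0.22 (microglia-like NF-kB) and -0.16 (endothelial-like myelin). Members at 5 CPM or more gave 0.57 (microglia-like MHC class II), -0.27 (oligodendrocyte-like astrocyte homeostasis), -1.76 (neuron-like homeostatic), -0.92 (microglia-like myelin) and -4.02 (neuroblast-like myelin).

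In the Ccl4-led microglia-like cluster alone, 15 named genes were shared and myelin was -0.15. In the P2ry12-led cluster alone, Cd74 (-0.41) and NF-kB (-0.028) turned, MHC class II was 0.003, heat shock -0.27 and immediate early 0.15, and 9 named genes were shared. Without the border macrophage cells, Cd74 (-0.173) and MHC class II (-0.023) turned in microglia-like cells. These settings were added after the data had been seen.

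Shares per cell without thinning differed by -0.039 (oligodendrocyte-like astrocyte homeostasis), -0.0188 (astrocyte-like myelin), -0.0224 (endothelial-like myelin) and -0.002 points (astrocyte-like pan-reactive). Thinned to 1000 UMIs they differed by 0.1 (endothelial-like MHC class I), -0.1 (oligodendrocyte-like astrocyte homeostasis) and 0 points (endothelial-like activation, microglia-like heat shock and oligodendrocyte-like immediate early).

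None of the main results shifted with Leiden resolution 0.5, a prior of 1 CPM, all barcodes, or stress genes left out of the total or of clustering. Of the values of single genes and other side results, 28 moved without turning over all settings and 535 did not move, and of the main results 805 did not.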

Other observations

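By their median, genes that glucocorticoids are known to induce were lower in the Mr1-/- library in all 5 large classes. Over genes picked after their ratios had been seen, which include Fkbp5, Sgk1, Ddit4 and the leucine zipper gene Tsc22d3, medians were -0.68 in endothelial-like, -0.68 in oligodendrocyte-like, -0.47 in microglia-like, -0.44 in mural-like and -0.36 in astrocyte-like cells. Tsc22d3 had ratios of 0.549 in microglia-like, 0.583 in mural-like, 0.595 in astrocyte-like, 0.601 in endothelial-like and 0.733 in oligodendrocyte-like cells. In microglia-like cells 5 of the 6 measured genes of this first set were lower. Of these 6 genes, Sgk1 (log2 ratio -0.04), Cebpd (-0.07) and Dusp1 (0.09) were near 0 there. The microglia-like median therefore rested on Ddit4, Fkbp5 and Tsc22d3. Further induced genes, picked without their ratios as a list having been looked at, had medians of -0.35 in oligodendrocyte-like, -0.34 in endothelial-like, -0.30 in mural-like, -0.22 in astrocyte-like and -0.15 in microglia-like cells. For these further genes the smaller classes had medians inside the random range, at -0.07 in neuron-like and 0.24 in neuroblast-like cells. Of the genes first seen, Dusp1 and Cebpd are also in the immediate early list and Fkbp5 in the A1-type list. Of the further genes, lists already examined hold Nfkbia (NF-kB), Mt1 and Mt2 (antioxidant), Lcn2 (pan-reactive and activation), Slc10a6 (A2-type) and Zbtb16 (MAIT-associated). Without these 6 genes, the medians were -0.43 in endothelial-like, -0.40 in oligodendrocyte-like, -0.30 in mural-like and -0.19 in astrocyte-like cells, all below the random range, and -0.075 in microglia-like cells, inside it.

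Of 3584 genes measured in all 5 large classes, 10 had a log2 ratio of at least 0.3 in size with the same sign in each. The lower genes were mt-Atp6 (median -1.15), Mrps6 (-0.82), Tsc22d3 (-0.74), Mpv17 (-0.64), Emc8 (-0.58) and Lars2 (-0.41). Among the higher genes were mt-Atp8 (0.73), Dynlt1b (0.44) and Rtl8b (0.37). In the Mr1-/- library 5 of 5107 cells (0.0979%) carried transcripts of the pineal gland, among them Tph1 (140 UMIs), an enzyme of serotonin synthesis, and the transcription factor Crx (39 UMIs). No such cell was among 5992 Mr1+/+ cells (up to 0.0501%). Aanat, a pineal enzyme of melatonin synthesis, had 0 UMIs. Asmt, another such enzyme, gave 13 UMIs in 4 of the 5 cells and 0 UMIs in the other cells of both libraries.

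The tests of dissociation stress, of induced genes in no examined list, of deep cells as the whole cause and of the glucocorticoid genes already seen were chosen only after the result had been seen. For glucocorticoid exposure, the further induced genes lay at or below the random range in 5 of 5 large classes, and those in no examined list in 4, not in microglia-like cells, which is in line with lower exposure of the Mr1-/- mice or cells. For time of day of collection, clock genes of the Dbp phase lay within 0.15 of 0 in 2 classes, and at -0.40 in endothelial-like (opposite phase not measurable), -0.52 in mural-like (opposite phase 0.14) and -0.50 in neuron-like cells (0.57), so it stays open. For dissociation stress, immediate early genes lay above the range where induced genes lay below it in 2 classes, microglia-like and oligodendrocyte-like, but heat shock genes lay below the range in 4, and its reading was set to open once these were seen. For deep cells as the whole cause, only the induced genes first seen were tested. Their medians stayed at -0.227 or lower in all 5 classes with each cell weighing the same or thinned. These genes were picked for their low ratios in the same cells, so this argues against that cause for these genes only. Deep cells or cell mix as part of it stay open (astrocyte-like cells kept 0.632 after thinning, the other classes at least 0.82), as does genotype with 1 library each.

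For the genes that pointed the same way in 5 classes, the test of a segment that holds the genes was chosen only after the result had been seen. For a strain-derived segment around Mr1, 0% of 10 genes lay within 20 Mb of Mr1 (interval up to 30.9%), against 1.42% of the 3584 genes. For reads shared with an overlapping gene, 60.0% of the 10 genes (26.2 to 87.8) had exons overlapping another gene, against 40.7% of the 3584. A segment around Mr1 that holds these genes was argued against, since 0 of the 10 lie on chromosome 1, the chromosome of Mr1. This covers only genes measured in all 5 classes. Gm10138, higher in Mr1-/- microglia-like cells (ratio 1.48), lies on chromosome 1 from 151339604 to 151345231, within 20 Mb of Mr1. For that gene such a segment stays open. Effects of such a segment on genes elsewhere, and shared reads, may still contribute, and genotype is untested.

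For the pineal cells, the test of free RNA and the list of pineal genes already seen were chosen only after the result had been seen. For cells of the pineal gland in the dissection, the 5 cells carried a mean of 10.2 of 18 further pineal genes, against 0.115 in other neuron-like cells, which is in line with whole cells from the gland. For free RNA from pineal cells, 3 or more of the genes first seen sat together in 5 cells, and 0.009% of the other cells carried 2 or more of them. These genes were picked because their UMIs lay in the same 5 cells. The test could hardly turn out otherwise, so no conclusion on free RNA is drawn from it. Many of these genes are shared with the retina, which was not tested. Genotype is untested here too, because 1 dissection per genotype could differ by these 5 cells alone.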
